A study of Mus musculus with 18 samples.

How the data were processed

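The study deposited gene-level RNA-seq values for 18 mouse libraries: 2 of wild-type R1 embryonic stem cells (mESC_WT) and 16 of cerebral cortex from male C57BL/6J mice, wild type or labelled Mcph1KO, at E17.5, P4 and the stages labelled A6w and A18w, with 2 libraries per group. Per the labels, cortex homogenate was divided for DNA and RNA isolation and libraries were made with an NEBNext Ultra RNA kit and sequenced on a HiSeq 2500. Groups and replicate numbers came from the labels alone. Genotypes are written as labelled, because the Mcph1 counts did not show a loss.

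The deposited values are estimated counts per gene, which the authors made with Salmon 1.4.0 after trimming with Trimmomatic 0.39 and quality control with FastQC, per the submitters' processing notes, on GRCm38.p6. They arrived as whole numbers for 54281 genes, so no further rounding was applied, and reads that fit several transcripts or genes had been shared out by the estimate. Of the gene IDs, 54107 were matched to a symbol by the GENCODE mouse release M21 table (53544 with the same version), and 174 stayed without. Total counts ran from 23531045 to 32041849 per library, and 22318 to 25407 genes had at least 1 count in a cortex library. No 2 libraries of a group were copies: their counts differed far more than sampling error allows (chi-square per degree of freedom 28.59 to 125).

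Genes were tested with edgeR 4.0.16 in R 4.3.3: filterByExpr (minimum count 10, minimum total count 15), TMM factors, a quasi-likelihood fit with 1 mean per group, quasi-likelihood F tests and Benjamini-Hochberg adjustment over all genes tested, with a call at an adjusted p under 0.05. The 16 cortex libraries were fitted together (19199 genes, 8 residual degrees of freedom, prior degrees of freedom 4.89, biological coefficient of variation 0.246). Stem cells were compared with E17.5 WT in a fit of the 10 wild-type libraries (19466 genes, 5 residual degrees of freedom). The comparisons were the libraries labelled Mcph1KO against WT at each stage and averaged over the stages, genotype by stage, the 3 steps between stages within each genotype, and stem cells against E17.5 WT cortex. The p-values measure the spread between libraries, since the labels do not say whether each library is a separate animal. CPM are TMM-scaled within each fit, except where stated and for the sex-linked genes, which were scaled by total count.

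Named genes followed a rule. Mcph1 came first. Then came, per comparison, called genes whose groups did not overlap (averaged comparison: the same sign at all 4 stages) and whose mean CPM was at least 1 in either group, the 8 largest rises and falls for genotype comparisons and the 5 largest for the others. Genes known only by a clone or model name were counted and not named. For each list described, up to 4 members were named: the called ones of smallest adjusted p or, where none was called, those of highest mean CPM. Angpt2 and sex-linked genes were also named. The comparisons, the rule, most alternatives and 39 gene lists of cell types, tissues and processes were fixed before the data were examined. Lists with at least 5 measured genes were tested with camera from limma 3.58.1 on log2 CPM (prior count 2), with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over lists. The correlation estimated for each list served as the alternative, and its adjusted p stands beside each call it ended. Medians were also computed with members at their bounds where a group had almost no counts. Where a group had 0 counts the fold is a lower limit from 3 counts over the group, and with 1 to 3 counts a ratio with its exact counting interval. Such limits and intervals cover counting error only.

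The method was tested on simulated data with 100 genes changed 2-fold and 100 changed 4-fold, at the fitted dispersions. edgeR recovered 29% of the 2-fold and 80% of the 4-fold changes in a genotype comparison at E17.5, 80% and 99% in the averaged comparison, 4% and 59% for genotype by stage, 25% and 87% for WT P4 against E17.5 and 3% and 79% for stem cells against cortex, with no sign wrong where a sign applies. It called 4 to 7 unchanged genes per comparison, and DESeq2 called 30 to 59. A list of 20 genes raised 1.5-fold was called with the preset and with the estimated correlation in each of the 4 comparisons tried, and no other list was. The simulated genes varied independently of each other, so this does not test the preset correlation or false list calls in real libraries. A 2-fold change in a single gene at a single stage would thus often be missed here.

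Alternatives were DESeq2 1.42.0, other size factors, no filter on low counts, only the 4 libraries compared, all 18 libraries, the replicate number as a block, each library left out in turn, and, chosen after the data were seen, both E17.5 or both A18w libraries numbered 1 left out. Exact permutation of genotype labels within stages was used for Mcph1. Exon-level or allele-level values were not analysed here, and 2 gene IDs that share the symbol Pcdha11 are not reported by name. Some genes that the naming rule picks are not reported here.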

Results

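Bulk RNA sequencing of male mouse cerebral cortex covered wild-type (WT) libraries and libraries labelled Mcph1KO at E17.5, at P4 and at the stages labelled A6w and A18w. Wild-type R1 embryonic stem cells (mESC) were measured beside them, and each of the 9 groups held 2 libraries. Stage dominated the 16 cortex libraries. The first principal component held 65.3% of the variance and set E17.5 (-117.8 to -133.7) and P4 (-57.82 to -85.61) apart from A6w and A18w (89.59 to 109.1). The second component (9.4%) set the P4 libraries (50.38 to 57.19) apart from all others (-71.5 to 3.588). It also set the E17.5 libraries numbered 1 (-63.99 in WT, -71.5 labelled Mcph1KO) apart from those numbered 2 (-14.74 and -11.84). Both genotypes lay close together within each number. Log2 CPM (counts scaled to library size) of the 2 libraries of a group correlated at 0.968 to 0.979. Y-linked transcripts were present in every cortex library (Ddx3y 41.6 to 68 CPM, Kdm5d 12.3 to 42.1, Eif2s3y 10.4 to 50), and Xist, the RNA that silences an X chromosome in female cells, reached at most 0.99 CPM.

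**Figure D1:**
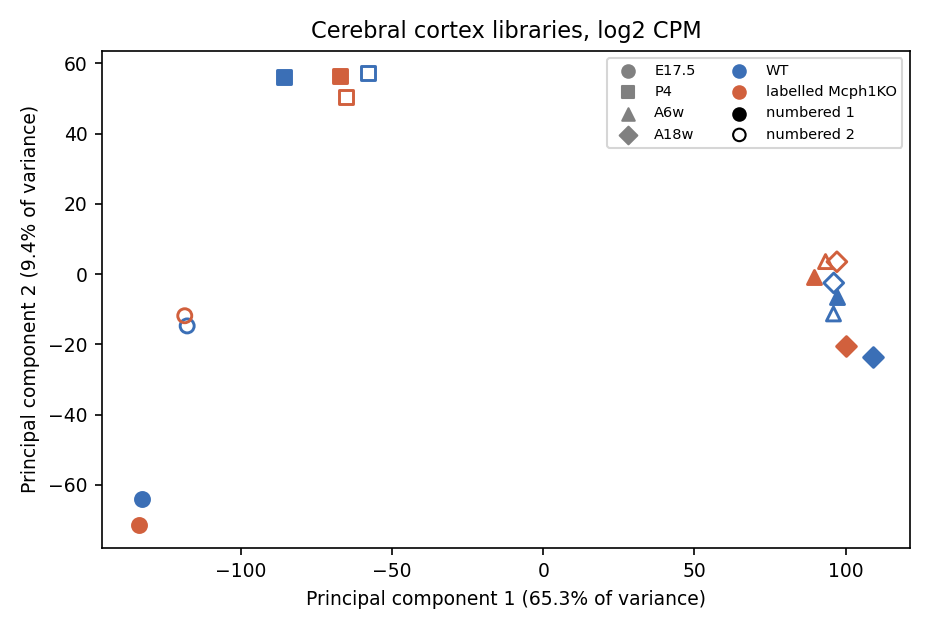
Principal components 1 (65.3% of variance) and 2 (9.4%) of log2 CPM in the 16 cortex libraries, 1 point per library, with marker shape for stage, colour for genotype label and filled or open points for libraries numbered 1 or 2. Component 1 sets E17.5 and P4 apart from each other and from A6w and A18w, which overlap (89.59 to 97.3 and 96.1 to 109.1). On component 2 the P4 libraries (50.38 to 57.19) lie at one end and the E17.5 libraries numbered 1 (-63.99 and -71.5) at the other.

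Mcph1 itself, which encodes microcephalin, was not lower in the libraries labelled Mcph1KO. The gene (ENSMUSG00000039842.15, GRCm38 chromosome 8, 18595131 to 18803189) was counted at 12.7 CPM (SD 0.707) against 11.3 (SD 1.7) in WT at E17.5, 14 (SD 0.919) against 11.5 (SD 1.13) at P4, 16.4 (SD 0.283) against 9.34 (SD 0.453) at A6w and 12.8 (SD 1.56) against 9.04 (SD 0.962) at A18w. In log2 terms these differences (here and below ± standard error, n = 2 libraries per group) were 0.17 ± 0.19, 0.29 ± 0.19, 0.81 ± 0.19 and 0.50 ± 0.19. Averaged over the 4 stages the difference was 0.44 ± 0.09 (unadjusted p = 0.000441, adjusted p = 0.368). The test of genotype by stage gave Mcph1 an unadjusted p = 0.139. Of the 8 libraries labelled Mcph1KO, 7 held more Mcph1 than both WT libraries of their stage. An exact permutation test that exchanged the labels within stages found a difference at least this large in 4 of 1296 labelings (two-sided p = 0.00309, smallest possible 0.00154). Gene totals do not show which exons were present, so they do not tell whether the libraries labelled Mcph1KO held an intact transcript. Stem cells held 82.3 CPM (SD 3.68), scaled in the separate fit of the wild-type libraries. Scaled by total count alone, stem cell libraries held 70.1 to 81.6 CPM and cortex libraries 7.39 to 16.

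Averaged over the 4 stages, 10 genes differed between the genotype labels. Of these, 5 were alternative first-exon genes of the protocadherin alpha cluster, whose products are neuronal adhesion molecules. Pcdha2 (18, 36939205 to 37187657) was higher in the libraries labelled Mcph1KO by a log2 fold change of 1.32 ± 0.10 (29.1 against 13.2 CPM, adjusted p = 0.000169). So were Pcdha1 (1.28 ± 0.20, 10.7 against 4.58 CPM, adjusted p = 0.0418) and Pcdha3 (0.66 ± 0.10, 24.8 against 16.2 CPM, adjusted p = 0.0398). Pcdha6 (-1.72 ± 0.18, 5.04 against 15.7 CPM, adjusted p = 0.0035) and Pcdha9 (-1.18 ± 0.14, 10.9 against 25.8 CPM, adjusted p = 0.0051) were lower. The direction was the same at each stage, as the naming rule asks. None of the 5 passed at a single stage (smallest adjusted p 0.0544, Pcdha2 at A18w). Pcdha2 measured 31.8 CPM (SD 5.16) against 13.6 (SD 1.63) at E17.5 and 54.7 (SD 5.23) against 28.8 (SD 6.22) at P4. It measured 16.9 (SD 0.566) against 6.02 (SD 0.94) at A6w and 13.2 (SD 1.34) against 4.15 (SD 0.156) at A18w. Members looked at after these calls did not pass: Pcdha8 (1.02 ± 0.35), Pcdha4 (0.54 ± 0.19), Pcdha5 (0.08), Pcdha7 (0.05), Pcdha12 (-0.13), Pcdhac1 (-0.19) and Pcdhac2 (-0.13), each at an adjusted p of 1. Summed over its 14 measured genes the cluster was level, at 304 against 295 CPM (0.06 ± 0.09, unadjusted p = 0.538). The cluster's genes share their last exons, so how reads were assigned among members is uncertain.

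The other 5 genes lay elsewhere. Sycp1, which encodes a component of the meiotic synaptonemal complex (3, 102818499 to 102936100), was counted 10 to 97 times in each of the 8 libraries labelled Mcph1KO, 0 times in 7 WT libraries and 5 times in A18w_WT replicate 2 (adjusted p = 0.00939). Uba1y, a Y-linked ubiquitin-activating enzyme (Y, 818649 to 844224), rose by 1.90 ± 0.26 (1.41 against 0.395 CPM, adjusted p = 0.0175). Its reads are uncertain because a close copy lies on the X chromosome. The last 3, known only by clone or model names, were higher as well: 2 lie on chromosome 12, and 1 is an annotated transcribed pseudogene 1.58 Mb from Mcph1. edgeR found 425 of 19199 genes at an unadjusted p under 0.05, fewer than the 960 that chance gives. That chance value ignores that same-numbered libraries of a stage deviated together to differing degrees (correlation 0.0829 to 0.478). edgeR with the replicate number as a block called 16 genes, all 10 among them. DESeq2 called 31 genes, all 10 among them. The count was 5 without P4_Mcph1KO replicate 1 and 6 without each of E17.5_WT replicate 1, E17.5_Mcph1KO replicate 2, P4_WT replicate 2, A6w_WT replicate 2 and A6w_Mcph1KO replicate 2. Pcdha2, Pcdha6 and Pcdha9 kept their calls without any single library. Sycp1 lost its call without P4_Mcph1KO replicate 1. With each of the 16 libraries left out in turn, Pcdha1 lost its call 15 times, Pcdha3 14 times and Uba1y 11 times. In tests chosen after results were seen, Pcdha2 (adjusted p = 0.00365) was the 1 gene called without both E17.5 libraries numbered 1, where Pcdha6 and Pcdha9 (0.0616 each) and Sycp1 (0.0629) lost their calls, and 5 genes were called without both A18w libraries numbered 1.

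**Figure D2:**
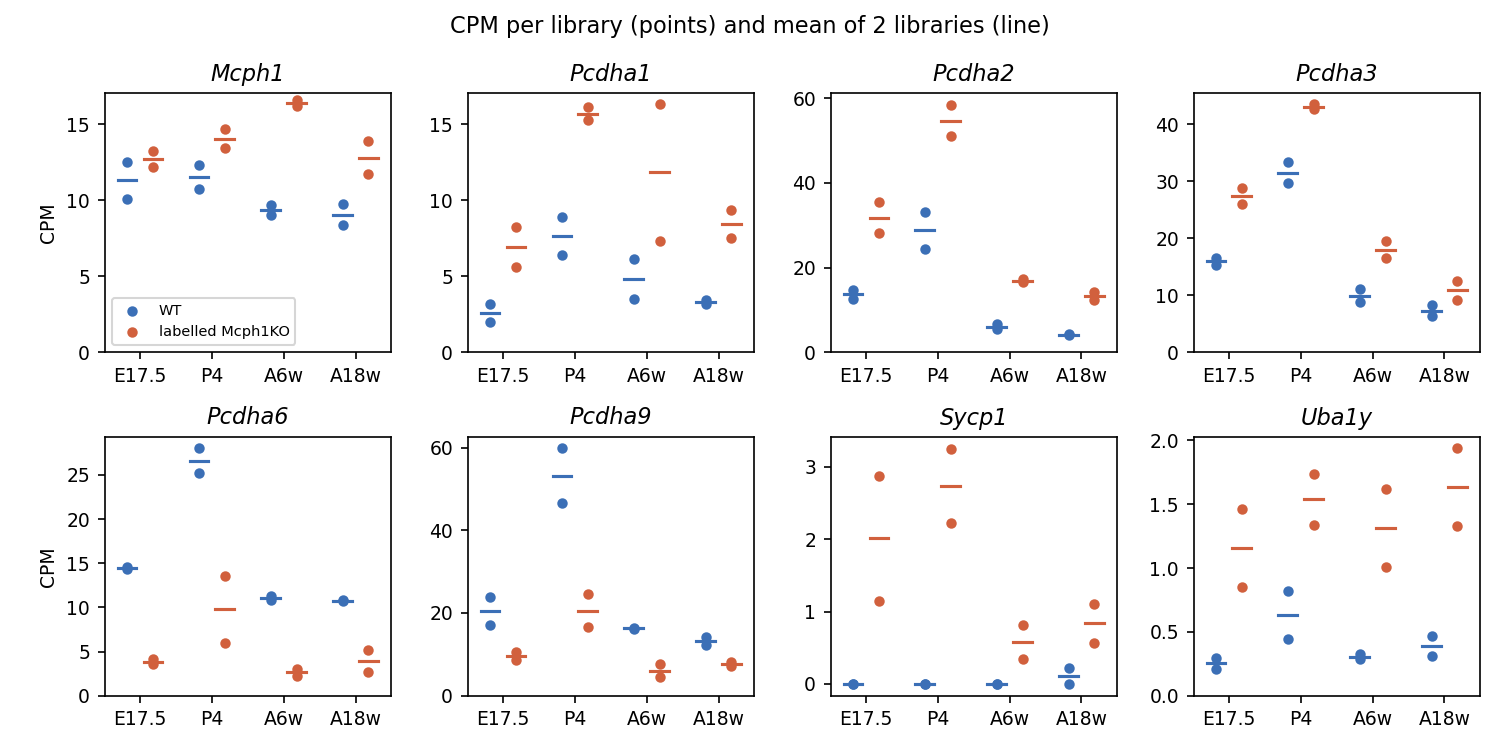
CPM of Mcph1 and of named genes from the averaged genotype comparison at the 4 stages, with 1 point per library and lines at the mean of 2 libraries, WT in blue and labelled Mcph1KO in orange. Pcdha2 is higher and Pcdha6 lower in the libraries labelled Mcph1KO at each stage (Pcdha2 at A18w 13.2 against 4.15 CPM), and Mcph1 is not reduced.

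Among fixed gene lists averaged over the stages, myelin genes were lower in the libraries labelled Mcph1KO. Of 18 measured oligodendrocyte and myelin genes 17 lay below 0 (median -0.27, camera adjusted p = 3.39e-07, adjusted p = 0.987 with an estimated correlation), such as Mbp (-0.28 ± 0.17) and Cnp (-0.20 ± 0.14). None passed on its own, and 0 did when adjusted over the list alone. Of the single stages the list passed at P4 and A18w, and not at E17.5 or A6w. Its genotype difference lay lower at A18w than at E17.5 (median -0.596, camera adjusted p = 2.27e-06, adjusted p = 0.983 with an estimated correlation). Immediate-early genes, which neurons switch on when active, lay higher (15 of 17 above 0, median 0.18, adjusted p = 4.83e-05, adjusted p = 0.987 with an estimated correlation), for example Arc (0.27 ± 0.13). This average reflects A6w (median 1.09), as the list's median was -0.04 at E17.5 and P4 and -0.10 at A18w. Both calls held without each of the 16 libraries in turn, with a highest adjusted p of 0.00666 for myelin and 0.0232 for immediate-early genes, each without A6w_WT replicate 1. Microglial genes (median 0.12, adjusted p = 0.00365), choroid plexus genes (-0.71, 0.00708) and genes of intermediate progenitors (0.18, 0.038) also passed, each with an adjusted p = 0.987 with an estimated correlation. They lost their calls without single libraries: microglia without replicate 1 labelled Mcph1KO of P4 (0.694), A6w (0.189) or A18w (0.132). Choroid plexus genes lost theirs without A18w_WT replicate 2 (0.743), P4_WT replicate 1 (0.165) and replicate 1 labelled Mcph1KO of E17.5 (0.472), P4 (0.224) or A18w (0.132). Intermediate progenitor genes lost theirs without replicate 1 labelled Mcph1KO of E17.5 (0.539), P4 (0.187), A6w (0.115) or A18w (0.205) and without WT replicate 2 of E17.5 (0.28), P4 (0.368), A6w (0.127) or A18w (0.135). Leaving out 1 library left the replicate numbers uneven between the genotype labels, so these losses do not tell the library from its number. Lists of cell division and genome stability did not pass: mitosis genes (median 0.04, adjusted p = 0.833) and S phase genes (0.01, 0.858). Nor did condensin subunits (0.02, 0.702), primary microcephaly genes (0.01, 0.906), p53 targets (0.02, 0.584) and DNA damage response genes (0.07, 0.0631). Radial glia genes (median -0.01, mean 0.02 with the test pointing up, 0.906) did not pass either, and nor did upper-layer (-0.08, 0.43) and deep-layer neuron genes (0.05, 0.438).

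At E17.5 edgeR called no gene between the genotype labels and DESeq2 called 11, and several lists leaned one way. Of 25 imprinted genes 24 lay above 0 (median 0.32, adjusted p = 3.63e-05, adjusted p = 0.998 with an estimated correlation), such as Igf2 (0.45 ± 0.61) and Rian (0.18 ± 0.17). All 27 mitosis genes lay above 0 (median 0.24, adjusted p = 0.00725, adjusted p = 0.998 with an estimated correlation), among them Top2a (0.24 ± 0.43), Mki67 (0.25 ± 0.42), Ccna2 (0.20 ± 0.42) and Tpx2 (0.29 ± 0.29). The mitosis list turned to lower, without passing, when E17.5_Mcph1KO replicate 1 (0.436) or E17.5_WT replicate 2 (0.108) was left out. DNA damage response genes (median 0.19, adjusted p = 0.00187), pericyte genes (0.22, 8.47e-05), interferon response genes (0.20, 0.00666) and heat shock genes (0.14, 0.0184) lay higher. So did meningeal fibroblast genes (0.48, 0.0176, with Col3a1 at 0.54 ± 0.41) and thalamic and hypothalamic genes (0.23, 0.00777). Genes of immature neurons (-0.15, 0.00777, with Tubb2b at -0.19 ± 0.17), ribosomal protein genes (-0.11, 0.00737) and choroid plexus genes (-1.19, 3.63e-05, with Ttr at 208 against 780 CPM) lay lower. Each of these 11 lists had an adjusted p = 0.998 with an estimated correlation, and 0 members passed, over all genes or when adjusted over the list alone. None held without every library, though leaving out 1 library also left the replicate numbers uneven between the genotype labels. Leaving out E17.5_Mcph1KO replicate 2 ended the calls of imprinted (adjusted p = 0.5), pericyte (0.0848), interferon (0.136), immature neuron (0.654) and thalamic genes (0.766), and reversed ribosomal protein genes (0.0136). It also turned meningeal genes to lower (0.461). Without E17.5_Mcph1KO replicate 1 the choroid plexus call ended (0.774) and DNA damage genes turned to lower (0.875), as they did without E17.5_WT replicate 2 (0.258). Without E17.5_WT replicate 1 the calls of meningeal (0.593), ribosomal protein (0.845), thalamic (0.319) and immature neuron genes (0.0669) ended, and interferon genes turned to lower (0.052). The immature neuron call also ended without E17.5_WT replicate 2 (0.0662), and that of heat shock genes without each of the 4 (0.0592 to 0.174). edgeR called 0 of 19199 genes (303 at an unadjusted p under 0.05 where chance gives 960, smallest adjusted p 0.75). With the replicate number as a block edgeR called 7 genes. At this stage 20.2% of genes had non-overlapping groups where chance gives 33.3%. That chance value ignores that same-numbered libraries deviated together (correlation 0.478).

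At P4 many of the same lists leaned the other way, and again edgeR called no gene. Imprinted genes lay lower (24 of 25 below 0, median -0.45, adjusted p = 1.09e-05, adjusted p = 0.762 with an estimated correlation), for example Ndn (-0.67 ± 0.34) and Rian (-0.28 ± 0.17). Vascular and meningeal genes lay lower as well. They were endothelial genes (median -0.34, adjusted p = 0.000199, with Kdr at -0.70 ± 0.21 and Itm2a at -0.61 ± 0.23), pericyte genes (-0.53, 0.000356, with Rgs5 at -0.74 ± 0.24 and Vtn at -0.83 ± 0.28) and all 14 meningeal genes (-0.75, 0.000199, with Col1a2 at -0.86 ± 0.46). With an estimated correlation their adjusted p was 0.762, 0.762 and 0.821. Thalamic and hypothalamic genes (median -0.92, adjusted p = 0.000654, adjusted p = 0.762 with an estimated correlation) included Tcf7l2 at 162 and 11.1 CPM in the WT libraries and 9.05 and 4.18 in those labelled Mcph1KO. Haemoglobin and other red blood cell genes lay lower (median -0.97, or -1.01 with 1 member at its bound, adjusted p = 0.0183, adjusted p = 0.821 with an estimated correlation). Of the 10, 0 passed over all genes and 4 when adjusted over the list alone. Lower too lay myelin (-0.35, 0.0183), mitosis (-0.33, 0.0183) and interferon genes (-0.36, 0.0191). Ribosomal protein genes (0.21, 0.00228) and nuclear oxidative phosphorylation genes (0.18, 0.00729) lay higher. These last 5 lists had an adjusted p = 0.857 with an estimated correlation. Only the endothelial and meningeal calls held without each library (highest adjusted p 0.0159 each). Imprinted (0.147), thalamic (0.432), mitosis (0.868) and interferon calls (0.766) ended without P4_WT replicate 1, and pericyte (0.122) and myelin calls (0.543) without P4_WT replicate 2. Ribosomal (0.705) and oxidative phosphorylation calls (0.31) ended without P4_Mcph1KO replicate 1, and the red blood cell call (0.507) without P4_Mcph1KO replicate 2. Several calls ended without a further library too: thalamic (0.124), mitosis (0.134), interferon (0.675) and myelin calls (0.178) without P4_Mcph1KO replicate 2, the mitosis call (0.0534) without P4_Mcph1KO replicate 1, ribosomal (0.679) and red blood cell calls (0.341) without P4_WT replicate 2, and the oxidative phosphorylation call (0.254) without P4_WT replicate 1. edgeR called 0 genes (718 at an unadjusted p under 0.05 where chance gives 960, smallest adjusted p 0.94) and DESeq2 called 13. edgeR with the replicate number as a block called 5.

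At A6w immediate-early genes stood out. Of 17 measured members 16 were higher in the libraries labelled Mcph1KO (median 1.09, adjusted p = 6.29e-16, adjusted p = 0.0725 with an estimated correlation), and 10 passed when adjusted over the list alone against 0 over all genes. The dendritic mRNA Arc stood at 418 against 176 CPM (1.25 ± 0.26), and the transcription factor genes Nr4a1 at 186 against 87.4 (1.09 ± 0.32) and Egr1 at 639 against 347 (0.88 ± 0.40), while Egr3 lay at -0.23 ± 0.53. The call held without each library (highest adjusted p 2.31e-06, without A6w_WT replicate 1), and the list's mean log2 CPM was 4.76 and 5.74 in the WT libraries against 6.40 and 6.56 in those labelled Mcph1KO. Meningeal genes (14 of 14 above 0, median 0.53, adjusted p = 0.000919, with Dcn at 1.4 ± 0.61) and DNA damage response genes (0.22, 0.0196) lay higher. Hippocampal genes (-1.46, 0.0196, with Zbtb20 at -1.15 ± 0.49), striatal genes (-0.76, 0.0196), synaptic genes (-0.25, 0.0332, with Camk2a at -0.29 ± 0.32) and histone genes (-0.40, or -0.47 with 2 members at their bounds, 0.0391) lay lower. These 6 lists had an adjusted p = 0.972 with an estimated correlation. Without A6w_WT replicate 1 the calls of meningeal (0.816), striatal (0.421) and histone genes (0.421) ended, and hippocampal genes turned to higher (0.408). Hippocampal (0.156), striatal (0.101) and histone calls (0.386) also ended without A6w_Mcph1KO replicate 2. Synaptic genes lost theirs without A6w_Mcph1KO replicate 1 (0.673) and A6w_WT replicate 2 (0.349), and DNA damage genes without A6w_WT replicate 2 (0.135) and A6w_Mcph1KO replicate 2 (0.278). Hippocampal genes in A6w_WT replicate 1 lay 1.91 above the mean of the stage. edgeR called 0 genes (763 at an unadjusted p under 0.05 where chance gives 960, smallest adjusted p 0.139) and DESeq2 called 29. Without each of A6w_WT replicate 1 and A6w_Mcph1KO replicate 2 edgeR called 2. With all libraries and the replicate number as a block it called 4.

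At A18w all 18 myelin genes lay lower in the libraries labelled Mcph1KO (median -0.56, adjusted p = 4.17e-09, adjusted p = 0.905 with an estimated correlation). Mbp, the major myelin basic protein, was counted at 2390 against 4200 CPM (-0.81 ± 0.34), Mobp at 684 against 1270 (-0.89 ± 0.44) and Cnp at 295 against 422 (-0.52 ± 0.29). None passed alone, over all genes or when adjusted over the list alone, and the list kept its call without each library (highest adjusted p 0.00704, without A18w_WT replicate 1). Microglial genes lay slightly higher (17 of 18 above 0, median 0.21, adjusted p = 0.035, with Cx3cr1 at 0.40 ± 0.21), and choroid plexus genes lower (median -2.77, adjusted p = 7.39e-05). Both had an adjusted p = 0.99 with an estimated correlation. Choroid plexus genes turned to higher without A18w_WT replicate 2 (0.567), which held Ttr at 636 CPM against 0 to 12.6 in the other 3 libraries, and lost their call without A18w_Mcph1KO replicate 1 (0.111). The microglial call ended without A18w_Mcph1KO replicate 1 (0.976), A18w_WT replicate 1 (0.227) and A18w_WT replicate 2 (0.0765). The smallest adjusted p was that of Pcdha2 (1.67 ± 0.21, adjusted p = 0.0544). edgeR called 0 genes (326 at an unadjusted p under 0.05 where chance gives 960) and DESeq2 called 3. edgeR with the replicate number as a block called 4.

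Taken over all 19199 genes, the genotype differences at 1 stage had little relation to those at another. Log2 fold changes correlated between -0.0611 and 0.0683 (Pearson) and between -0.152 (E17.5 and P4) and 0.0544 (E17.5 and A18w, Spearman). Some lists passed in the same direction at 2 stages, such as myelin genes at P4 and A18w, choroid plexus genes at E17.5 and A18w, and meningeal and DNA damage genes at E17.5 and A6w, though none passed with an estimated correlation. The test of genotype by stage called 0 genes (435 at an unadjusted p under 0.05 where chance gives 960, smallest adjusted p 1), and DESeq2 called 8. edgeR with the replicate number as a block called 9.

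**Figure D3:**
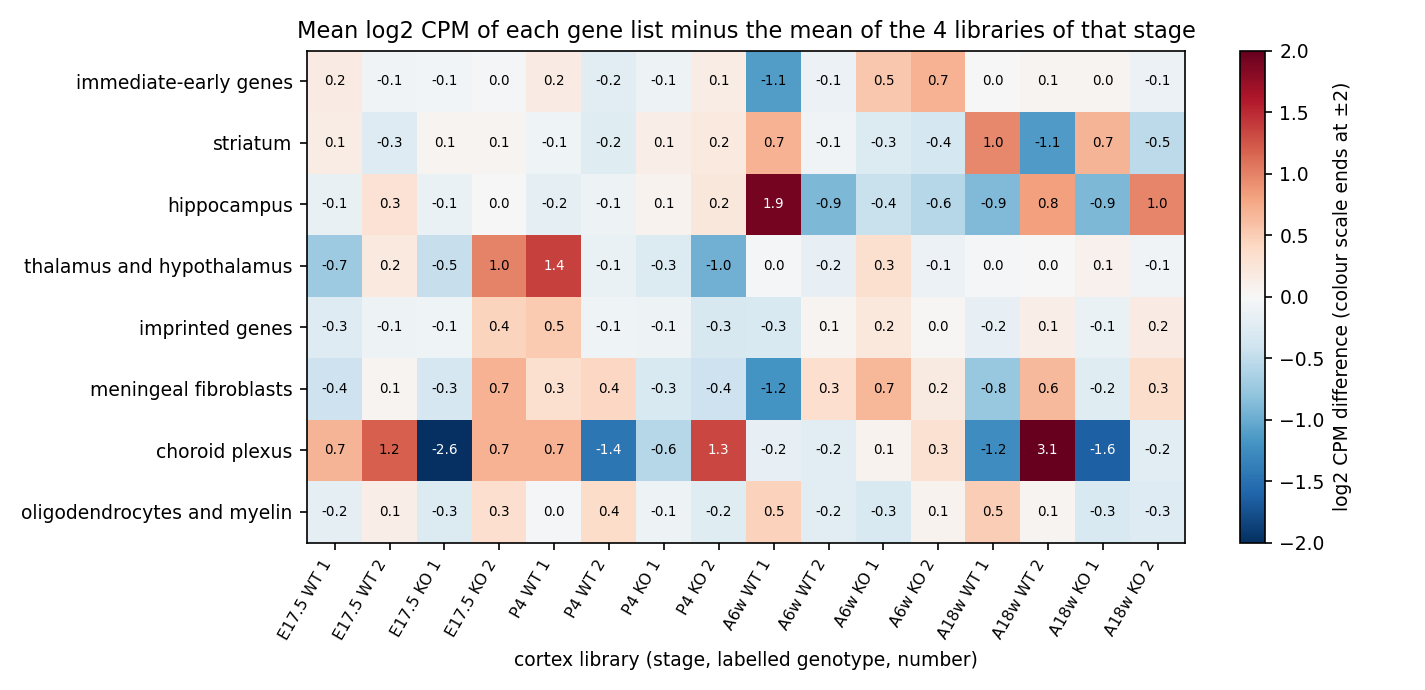
Heat map of gene lists (vertical) by the 16 cortex libraries (horizontal), each cell the list's mean log2 CPM minus the mean of the 4 libraries of its stage. Single libraries carry the largest deviations, such as choroid plexus genes in A18w_WT replicate 2 (3.10) and thalamic and hypothalamic genes in P4_WT replicate 1 (1.37).

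From E17.5 to P4 cell cycle transcripts fell and synaptic and glial transcripts rose in WT cortex. Of 27 mitosis genes 25 fell (median -1.62, adjusted p = 3.52e-10, adjusted p = 0.362 with an estimated correlation), including Tpx2 (-1.60 ± 0.30), Cdc20 (-1.94 ± 0.37) and Kif11 (-1.64 ± 0.36). Of 24 S phase genes 17 fell (median -1.30, adjusted p = 7.25e-09, adjusted p = 0.362 with an estimated correlation), such as Mcm2 (-1.77 ± 0.32) and Mcm4 (-1.27 ± 0.22). Of 10 intermediate progenitor genes 9 fell (median -2.54, adjusted p = 5.48e-08, adjusted p = 0.362 with an estimated correlation). The proneural factor Neurog2 went from 96.5 to 2.67 CPM (-5.19 ± 0.56) and Insm1 from 187 to 31.6 (-2.57 ± 0.29). Nhlh1 (-4.44 ± 0.64) and Mfng (-2.51 ± 0.33) fell with them. Primary microcephaly genes fell (11 of 26, 1 rose, median -0.81, adjusted p = 1.5e-06, adjusted p = 0.362 with an estimated correlation), with Lmnb1 at -1.54 ± 0.22, Ncapd2 at -1.36 ± 0.25 and Aspm at -1.80 ± 0.35. Condensin subunits fell too (7 of 8, median -1.35, adjusted p = 3.82e-05, adjusted p = 0.362 with an estimated correlation). Radial glia genes were split (10 fell, 2 rose, median -0.93, adjusted p = 0.000819, adjusted p = 0.362 with an estimated correlation): Nes (-1.87 ± 0.31) and Vim (-1.08 ± 0.17) fell, and Ptprz1 (0.87 ± 0.13) rose. Among Polycomb and chromatin genes 10 of 23 fell and 0 rose (median -0.58, adjusted p = 7.57e-05, adjusted p = 0.362 with an estimated correlation), among them Cbx2 (-2.14 ± 0.35) and the H3K27 demethylase Kdm6b (-1.25 ± 0.21).

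Synaptic genes rose over the same step (18 of 25, median 1.02, adjusted p = 7.25e-09, adjusted p = 0.362 with an estimated correlation): Nrgn from 28.4 to 306 CPM (3.43 ± 0.49), Camk2a from 53.4 to 231 (2.11 ± 0.34) and the vesicle calcium sensor Syt1 from 169 to 511 (1.59 ± 0.22). Astrocyte genes rose (11 of 16, median 1.2, adjusted p = 1.29e-05, adjusted p = 0.362 with an estimated correlation), led by the water channel Aqp4 (2.66 to 69.7 CPM, 4.73 ± 0.49), Ntsr2 (3.28 ± 0.30) and Acsbg1 (1.48 ± 0.25). Oligodendrocyte precursor genes rose (9 of 12, median 1.29, adjusted p = 4.52e-05, adjusted p = 0.362 with an estimated correlation), with Lhfpl3 at 1.48 ± 0.22 and Enpp6 29.7-fold higher (counting interval 9.79 to 147). Mitochondrially encoded genes rose (8 of 13, median 1.08, adjusted p = 4.52e-05, adjusted p = 0.362 with an estimated correlation), mt-Nd5 by 1.68 ± 0.27. Red blood cell genes fell (6 of 10, median -2.77, or -2.78 with 2 members at their bounds, adjusted p = 0.00018, adjusted p = 0.362 with an estimated correlation), such as the globin gene Hbb-bt (-3.11 ± 0.46), though reads of near-identical globin copies are uncertain. The largest rises included Cplx3 (5.57 ± 0.77). edgeR called 3502 genes, 1852 higher and 1650 lower, of which 1935 changed at least 2-fold. That count was 447 without E17.5_WT replicate 1 and 1132 without P4_WT replicate 2. Of 69 called genes picked by the naming rule 24 kept their call without each library. Of the genes given above, Mcm4 (adjusted p = 0.0581), Enpp6 (0.0626), Ncapd2 (0.0646), Mcm2 (0.0661), Tpx2 (0.0735) and Aspm (0.0758) lost theirs without E17.5_WT replicate 1, and Cdc20 (up to 0.0768) and Kif11 (up to 0.135) without either library.

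From P4 to A6w myelin genes showed the largest rise of any list in WT cortex (18 of 18, median 4.70, or 4.70 with 1 member at its bound, adjusted p = 1.06e-14, adjusted p = 0.335 with an estimated correlation). Mobp went from 0.176 to 958 CPM (12.4 ± 0.76), Mal from 1.53 to 298 (7.60 ± 0.38) and Opalin rose at least 355-fold. Synaptic genes rose further (23 of 25, median 1.77, adjusted p = 8.42e-11, adjusted p = 0.564 with an estimated correlation), including Snap25 (243 to 2610 CPM, 3.43 ± 0.23) and Camk2a (4.27 ± 0.37). Microglial genes rose (17 of 18, median 1.78, adjusted p = 2.34e-08, adjusted p = 0.564 with an estimated correlation), such as Tmem119 (2.74 ± 0.28), P2ry12 (2.92 ± 0.34) and Siglech (2.92 ± 0.32). Astrocyte genes rose (11 of 16, median 1.63, adjusted p = 2.28e-05, adjusted p = 0.564 with an estimated correlation), with the glutamate transporter Slc1a2 going from 253 to 3750 CPM (3.89 ± 0.27) and S100b from 2.67 to 92 (5.10 ± 0.47). Immediate-early genes rose (8 of 17, 1 fell, median 1.25, adjusted p = 0.0061, adjusted p = 0.564 with an estimated correlation), led by Arc (5 to 176 CPM, 5.14 ± 0.31), Junb (2.93 ± 0.31) and Egr1 (3.14 ± 0.44). Nuclear oxidative phosphorylation genes rose modestly (21 of 29, median 0.82, adjusted p = 1.94e-05, adjusted p = 0.568 with an estimated correlation), for example Sdha (1.36 ± 0.20).

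Genes of immature and migrating neurons fell over this step (16 of 19, median -3.01, adjusted p = 1.71e-12, adjusted p = 0.0794 with an estimated correlation). The microtubule protein Dcx went from 1480 to 23.1 CPM (-6.00 ± 0.20), Dpysl3 from 2870 to 49.4 (-5.86 ± 0.21), Tubb2b from 3910 to 120 (-5.03 ± 0.20) and Draxin from 99.5 to 1.64 (-5.93 ± 0.26). All 27 mitosis genes fell (median -3.05, adjusted p = 1.75e-12, adjusted p = 0.564 with an estimated correlation), such as Top2a (-5.05 ± 0.55) and Mki67 (-4.58 ± 0.52). DNA damage response genes fell (17 of 23, median -1.34, adjusted p = 1.24e-06, adjusted p = 0.564 with an estimated correlation), among them Bard1 (-3.87 ± 0.55). Of 26 primary microcephaly genes 16 fell and 1 rose (median -1.08, adjusted p = 7.01e-05, adjusted p = 0.564 with an estimated correlation), with Lmnb1 at -3.77 ± 0.24, Aspm at -4.58 ± 0.44, Stil at -4.39 ± 0.52 and Knl1 at -3.61 ± 0.47. Meningeal genes fell (13 of 14, median -2.45, adjusted p = 9.91e-05, adjusted p = 0.564 with an estimated correlation), Col3a1 from 115 to 6.16 CPM (-4.22 ± 0.48). Imprinted genes went both ways (15 fell, 3 rose of 25, median -1.32, adjusted p = 0.00301, adjusted p = 0.564 with an estimated correlation). The growth-related H19 (-9.44 ± 0.81) and Cdkn1c (-3.49 ± 0.32) fell, and Impact (2.16 ± 0.20) and Snrpn (1.17 ± 0.15) rose. Polycomb and chromatin genes were split (12 fell, 3 rose of 23, median -0.64, adjusted p = 0.0429, adjusted p = 0.681 with an estimated correlation). The methyltransferase Ezh2 went from 29.8 to 3.41 CPM (-3.12 ± 0.41) while Cbx7 went from 5.01 to 46.2 (3.21 ± 0.30). The radial glia genes Fabp7 (-4.53 ± 0.44) and Vim (-2.55 ± 0.18) fell. edgeR called 7967 genes, 4079 higher and 3888 lower (5128 at least 2-fold). Of 92 called genes picked by the naming rule 84 kept their call without each library.

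**Figure D4:**
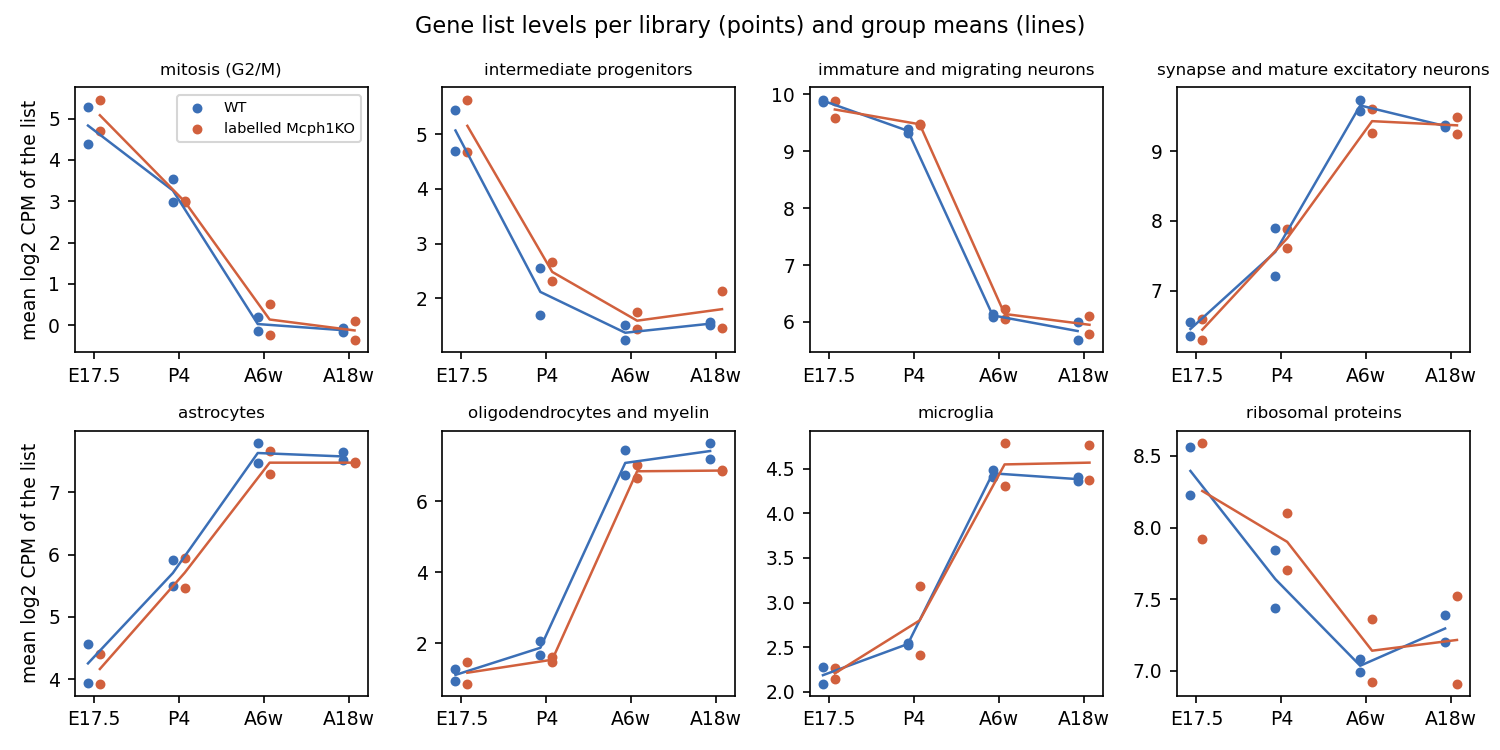
Mean log2 CPM of 8 gene lists at the 4 stages, with 1 point per library and lines through the means of 2 libraries, WT in blue and labelled Mcph1KO in orange. Myelin genes rise after P4 in both genotypes.

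From A6w to A18w in WT cortex edgeR called 5 genes (1196 at an unadjusted p under 0.05 where chance gives 960) and DESeq2 75. The stress kinase Sgk1 rose from 56.2 to 226 CPM (2.01 ± 0.21, adjusted p = 0.00571), and elastin (Eln, -2.15 ± 0.24) and the basement membrane collagens Col4a1 (-1.28 ± 0.18) and Col4a2 (-1.34 ± 0.17) fell. Rsc1a1, at least 66.3-fold higher, overlaps another gene and is uncertain. All 5 lost their call without A6w_WT replicate 2 and without A18w_WT replicate 1, with 0 genes then called, 2 without A6w_WT replicate 1 and 17 without A18w_WT replicate 2. Striatal genes lay higher at A18w (15 of 15 above 0, median 2.61, adjusted p = 1.06e-16, adjusted p = 0.386 with an estimated correlation). Of them 0 passed over all genes and 14 when adjusted over the list alone, with the dopamine signalling gene Ppp1r1b at 563 against 127 CPM (2.15 ± 0.66). Their mean log2 CPM was 6.52 and 4.43 in the A18w WT libraries numbered 1 and 2, against 3.64 and 2.87 at A6w. Immediate-early genes lay higher too (16 of 17 above 0, median 0.83, adjusted p = 9.57e-10, adjusted p = 0.308 with an estimated correlation), Arc at 424 against 176 CPM, 0 passing over all genes and 8 when adjusted over the list alone. Interferon response genes lay lower (median -0.90, adjusted p = 0.00699, adjusted p = 0.808 with an estimated correlation).

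The libraries labelled Mcph1KO passed through the same 3 steps. From E17.5 to P4 edgeR called 3594 genes (1953 higher, 1641 lower), of which 2282 were also called in WT, 2281 in the same direction, where 655.6 shared genes would come from independent lists. Log2 fold changes of all genes in the 2 genotypes correlated at 0.569 (Pearson, Spearman 0.715). Mitosis genes fell (26 of 27, median -2.22, adjusted p = 7.73e-15, adjusted p = 0.277 with an estimated correlation), Neurog2 went from 92.3 to 3.52 CPM (-4.71 ± 0.55), and Nrgn (3.87 ± 0.50), Aqp4 (5.06 ± 0.50) and Gfap (6.2 ± 0.86, 1.67 to 123 CPM) rose. The imprinted genes Grb10 (-1.83 ± 0.21), Plagl1 (-1.29 ± 0.18) and Mest (-2.42 ± 0.41) fell. The count was 676 without E17.5_Mcph1KO replicate 1, 1519 without P4_Mcph1KO replicate 1 and 1770 without P4_Mcph1KO replicate 2. Of 89 called genes picked by the naming rule 46 kept their call without each library. From P4 to A6w 7574 genes were called (3892 higher, 3682 lower). Of these 6032 were also called in WT, 6031 in the same direction (3143 from independent lists, Pearson correlation 0.761, Spearman 0.827). Mal (6.96 ± 0.37), Snap25 (3.25 ± 0.23), Tmem119 (3.10 ± 0.28), Dcx (-5.39 ± 0.19) and Lmnb1 (-4.07 ± 0.25) changed as in WT. Immediate-early genes rose here in 12 of 17 members (median 3.25, adjusted p = 1.44e-06, adjusted p = 0.315 with an estimated correlation), Arc from 6.06 to 418 CPM (6.11 ± 0.32). From A6w to A18w edgeR called 0 genes (870 at an unadjusted p under 0.05 where chance gives 960, smallest adjusted p 0.141) and DESeq2 60. Over this step log2 fold changes in the 2 genotypes correlated at 0.128 (Spearman 0.233), with 0 genes called in both. Immediate-early genes did not pass, with Arc at 317 against 418 CPM.

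Embryonic stem cells differed from E17.5 WT cortex in 13230 of 19466 genes (6367 higher, 6863 lower), 11457 of them at least 2-fold. All 21 measured pluripotency genes were higher (median 11.1, or 10.7 with 6 members at their bounds, adjusted p = 1.62e-12, adjusted p = 0.0503 with an estimated correlation). The core factor Nanog stood at 734 against 0.156 CPM (12.2 ± 0.43), and Dppa5a at 1110 against 0.502 (11.1 ± 0.49). Tdgf1, with 3 counts in the cortex group, was 28400-fold higher (counting interval 9720 to 138000). Also higher were Zfp42 at least 30800-fold and Fgf4 at least 3640-fold. All 24 S phase genes were higher (median 2.54, adjusted p = 2.37e-07, adjusted p = 0.326 with an estimated correlation), such as Ccne1 (5.29 ± 0.30) and Mcm5 (4.30 ± 0.28). DNA damage response genes (22 of 23 higher, 1 lower, median 2.86, adjusted p = 2.51e-06, adjusted p = 0.326 with an estimated correlation) included Bard1 (3.29 ± 0.28), and p53 targets (20 of 24 higher, 2 lower, median 2.0, adjusted p = 6.01e-05, adjusted p = 0.0503 with an estimated correlation) included Sesn2 (4.32 ± 0.20). Ribosomal protein genes were higher (37 of 40, 1 lower, median 1.69, adjusted p = 2.37e-07, adjusted p = 0.326 with an estimated correlation).

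Most measured neural genes were lower in the stem cells. All 19 genes of immature neurons were lower (median -5.03, or -5.03 with 3 members at their bounds, adjusted p = 4.81e-08, adjusted p = 0.0503 with an estimated correlation), Dcx at least 26600-fold and Neurod2 at least 6920-fold. All 25 synaptic genes were lower (median -5.27, or -5.27 with 1 member at its bound, adjusted p = 1.05e-08, adjusted p = 0.241 with an estimated correlation), with the glutamate receptor Gria2, counted 1 time in the stem cells, 9270-fold lower (counting interval 1660 to 366000). Interneuron genes were lower (16 of 19, 1 higher, median -7.89, or -8.11 with 1 member at its bound, adjusted p = 2.83e-06, adjusted p = 0.0503 with an estimated correlation), such as Dlx1 (-10.4 ± 0.42) and Gad1 (-5.91 ± 0.26). All 14 upper-layer genes were lower (median -6.39, adjusted p = 3.42e-06, adjusted p = 0.0921 with an estimated correlation), Pou3f2 by 6200-fold (counting interval 1110 to 245000). Of 15 deep-layer genes 10 were lower and 0 higher (median -7.33, or -7.33 with 1 member at its bound, adjusted p = 0.000126, adjusted p = 0.0921 with an estimated correlation), Tbr1 by 13500-fold (counting interval 2430 to 535000). Both Pou3f2 and Tbr1 had 1 count in the stem cells. The radial glia gene Lhx2 (-9.80 ± 0.46) was lower as well. Imprinted genes were mostly lower (20 of 25, 3 higher, median -3.43, or -3.43 with 1 member at its bound, adjusted p = 0.000295, adjusted p = 0.326 with an estimated correlation), including Nap1l5 (-8.16 ± 0.36) and Ndn (-5.50 ± 0.31). The comparison sets a cultured cell line against tissue of another strain, so cell type, growth condition and strain differ together. Of 115 called genes picked by the naming rule only Ttr lost its call without a single library.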

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

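Of the tests in this part, those of the summed Pcdha count, of genes near Mcph1, of exchanged libraries, of Angpt2 and of the relations between list levels were chosen only after results were seen.

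The 8 pairs of genotype effects given here were picked out because a gene list passed in opposite directions at 2 stages and a camera test of the difference passed too. Between E17.5 and P4 these were imprinted genes (median 0.32 at E17.5 and -0.45 at P4, adjusted p of the difference 3.83e-09), pericyte genes (0.22 and -0.53, 6.47e-07), meningeal genes (0.48 and -0.75, 1.81e-05), thalamic and hypothalamic genes (0.23 and -0.92, 1.81e-05), ribosomal protein genes (-0.11 and 0.21, 5.93e-05), interferon genes (0.20 and -0.36, 0.000379) and mitosis genes (0.24 and -0.33, 0.000412). Between P4 and A6w it was meningeal genes (-0.75 and 0.53, 9.51e-07). With an estimated correlation none of these differences passed (adjusted p = 0.329 to 0.953). Over 38 lists and 6 pairs of stages 57 differences passed with the preset correlation and 0 with the estimated one.

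Tissue carried along in single libraries may account for part of these opposite effects, a relation tested for imprinted genes alone and not for pericyte, ribosomal, interferon or mitosis genes. Over the 16 cortex libraries, as deviations from the stage mean, imprinted genes followed thalamic and hypothalamic genes (Pearson r = 0.847, permutation adjusted p = 0.0028) and meningeal genes (r = 0.73, adjusted p = 0.0015), the latter with 1 shared gene left out. Without the 2 libraries farthest from the median, P4_WT replicate 1 and E17.5_Mcph1KO replicate 2, the first r was 0.596, and without A6w_WT replicate 1 and A18w_WT replicate 1 the second was 0.742. Imprinted genes are strongly expressed in the hypothalamus and in mesenchyme, so both relations are in line with dissection or meninges differing between samples. The P4 meningeal call held without each single library, so a single library is not enough for that list, though the call did not pass with an estimated correlation. A genotype effect that turns over between E17.5 and P4 stays open.

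The 10 genes of the averaged comparison may reflect a real genetic difference between the groups, though not necessarily the loss of Mcph1. The libraries were split within stages in 100 ways, the labels included, out of 648 possible ones. Of the 100 splits 8 called at least 10 genes (highest other 137) and 46 called 0. By that count alone chance is not excluded. Of 39 other splits that followed the replicate numbers at E17.5, 7 reached 10. Of 60 further splits 0 did, with at most 4 genes. This points to a structure of the libraries along these numbers (with the number as a replicate block, 16 genes were called, all 10 among them). The genotype labels do not follow these numbers, so the count of 8 does not tell chance from this structure. The summed Pcdha count was level (log2 fold change 0.0595, SE 0.0941), which is in line with reads moved between first exons, as a sequence variant would do, and equally with altered promoter choice. Genes within 10 Mb of Mcph1 more often had an averaged p under 0.05 than genes elsewhere (14 of 147 against 399 of 19022, odds ratio 4.91, 95% interval 2.59 to 8.63, one-sided Fisher exact p = 3.69e-06). This could come from a segment of another strain kept around the altered locus or from effects of Mcph1 on its surroundings. The test treats genes as independent. Some of the 14 lie close together, at 0.838 to 1.88 Mb from Mcph1, and some had few counts, such as Grk1 (0.269 against 0.186 CPM). The interval and p may thus overstate the evidence.

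Mcph1 counts above WT in the libraries labelled Mcph1KO could mean exchanged libraries, reads of a neighbour or a transcript that persists without a working product. Judged at the 10 genes of smallest p over the other 3 stages, 0 of 16 libraries went against their label, so an exchange at single stages is unlikely, while an exchange of the 2 genotype names throughout would leave this result unchanged. Angpt2, which lies within Mcph1, had an averaged log2 fold change of -0.0978 (SE 0.237, upper limit 0.376) where 1.19 would be needed to supply the added counts. This covers a rise of Angpt2 itself, since Angpt2 reads counted only for Mcph1 would leave the Angpt2 value level. A transcript that lacks some exons and is still counted was not tested, as gene totals do not show exons.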

How the results depend on the processing

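Of the tests in this part, those without both E17.5 or both A18w libraries numbered 1, and those of gene lists without single libraries, were chosen only after results were seen. With an estimated correlation 0 of 159 gene list calls over all comparisons were left. Counts depended on tool, filter and library, and the cause was not tested unless stated. For the libraries labelled Mcph1KO against WT edgeR called 0 genes per stage. At E17.5 DESeq2 called 11 and edgeR without a filter 105, at P4 13 and 225, at A6w 29 and 262 and at A18w 3 and 107. With only the 4 P4 libraries the count was 1. Averaged, 10 became 31, 124, 1 without both E17.5 libraries numbered 1 and 5 without both A18w libraries numbered 1, and genotype by stage 0 became 8 and 466. Most genes called without a filter had also been tested with it (213 of 225 at P4, 123 of 124 averaged). WT P4 against E17.5 (3502) gave 1815 with 4 libraries and 713 without both E17.5 libraries numbered 1, and the same step labelled Mcph1KO (3594) gave 669. WT A18w against A6w (5) gave 75, 413, 0 with 4 libraries and 0 without both A18w libraries numbered 1, and labelled Mcph1KO (0) gave 60, 311 and 2.

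With 1 library left out in turn, fewer libraries remaining, counts ran from 0 to 1 at P4 (1 without P4_Mcph1KO replicate 2), 0 to 2 at A6w, 5 to 10 averaged, 0 to 2 for genotype by stage, 447 to 3000 and 676 to 3696 for P4 against E17.5 in WT and labelled Mcph1KO, 0 to 17 and 0 to 1 for A18w against A6w. They stayed 0 at E17.5 and A18w, and ran from 5754 to 7165 and 5410 to 5800 for A6w against P4 and from 11355 to 12495 for stem cells. The ribosomal protein list at E17.5 ranged from 4.95e-09 to 0.845 (without E17.5_WT replicate 1) and reversed without E17.5_Mcph1KO replicate 2 (adjusted p = 0.0136). Pcdha2 kept its averaged call under each alternative, while Pcdha6 and Pcdha9 (0.0616 each) and Sycp1 (0.0629) lost it without both E17.5 libraries numbered 1. Over all named genes and alternatives, 6604 fold changes kept their direction and side of the threshold, 389 lost a call, 51 gained 1 and 204 turned direction, called neither before nor after.

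The replicate number as a replicate block gave 7, 5, 4 and 4 genes at the 4 stages, 16 averaged and 9 for genotype by stage. Same-numbered libraries deviated together at 0.478, 0.209, 0.0829 and 0.295 (E17.5, P4, A6w, A18w), and 4, 3, 2 and 4 of 4 libraries lay closest to their own number. This hints at a shared origin of same-numbered libraries at E17.5 and A18w. The low correlation at A6w does not exclude one there. On the third principal component (3.5% of variance) the A6w libraries lay at 0.6558 (WT) and -3.5 (labelled Mcph1KO) when numbered 1. Those numbered 2 lay at 39.23 and 39.12. The numbers were not taken as pairs, because the labels do not tie them and the correlation at A6w stayed under the 0.1 asked of every stage. Depth limits genes of few counts, such as Sycp1.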

Other observations

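No tests were added for this part, and its values were chosen only after results were seen.

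Mean log2 CPM of the immediate-early list was 4.76 and 5.74 in A6w WT, 6.40 and 6.56 in A6w labelled Mcph1KO, 6.21 and 6.26 in A18w WT and 6.25 and 6.08 in A18w labelled Mcph1KO. Arc measured 156 and 196 CPM in A6w WT, 336 and 500 in A6w labelled Mcph1KO, 521 and 328 in A18w WT and 317 and 317 in A18w labelled Mcph1KO.

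Markers of other brain regions varied between single libraries and, at E17.5 and A18w, also between libraries numbered 1 and 2 in both genotypes. Choroid plexus Ttr ranged from 1.24 to 899 CPM at E17.5, from 0.858 to 736 at P4 and from 0 to 636 at A18w. Thalamic Tcf7l2 reached 143 and 93.5 CPM in the E17.5 libraries numbered 2 against 7.83 and 9.43 in those numbered 1, and 162 in P4_WT replicate 1 against 4.18 to 11.1 in the other 3. Striatal genes lay at a mean log2 CPM of 6.52 and 6.24 in the A18w libraries numbered 1 against 4.43 and 5.03 in those numbered 2.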
